A study of Homo sapiens with 16 samples.

How the data were processed

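The samples are human breast cancer cell lines: HCC1806 and BT474 as monolayers and as spheroids 10 and 20 days after seeding, and CAL148 and ZR-75-30 as monolayers, 2 libraries per group, 16 in all. Groups were taken from the sample titles, because a treatment label names the monolayer culture for all 16 samples, 8 spheroid libraries included. Per the labels the libraries are poly(A)-selected RNA sequenced as 150 bp read pairs, from cells in RPMI (HCC1806, ZR-75-30) or DMEM (BT474, CAL148) with 10% serum, so line and medium cannot be separated between these pairs. Subtype is general knowledge, not a label. The labels do not say whether replicates are separate cultures, so p measures only the spread between these samples.

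Per the submitters' processing notes the authors aligned reads to GRCh38 with HISAT2 2.2.1 and counted them per gene with featureCounts 2.0.6. The strand setting and the handling of reads with several alignments are not given. The deposited counts are whole numbers for 58735 genes, all found in GENCODE 29 by ID, symbol and position. Low counts are mostly even (1.60 to 2.13 even for each odd), as when both mates of a pair are counted. Near-identical genes (KRT6A and KRT6B, SERPINB3 and SERPINB4, the histone, LCE, SPRR and HLA genes) may share or lose reads. The deposited FPKM file holds values the authors made from the same counts, with a size factor per library times 38.4 M as denominator. FPKM served for 2 alternatives alone.

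Tests used R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with minimum count 10 and total count 15, robust quasi-likelihood F tests), limma 3.58.1 and DESeq2 1.42.0, and figures matplotlib 3.10.9. Before the data were examined 1 fit of the 12 HCC1806 and BT474 libraries in 6 groups (20929 genes tested) was chosen for 8 comparisons: day 10 and day 20 spheroids against monolayer and day 20 against day 10 in each line, and the line difference in the effect at each day. Subtype was tested on counts summed per line. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. Day 10 and day 20 share their monolayers, so the days are compared in the direct test alone.

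Gene lists, 39 with 825 symbols (823 matched), were fixed beforehand from general knowledge: breast stem cell and pluripotency markers, hypoxia response, glycolysis, nuclear oxidative phosphorylation genes, mitochondrially encoded proteins, mitosis, DNA replication, cell cycle arrest, epithelial junctions, mesenchymal genes, basal and luminal markers, the ERBB2 amplicon, squamous differentiation, cholesterol and fatty acid synthesis, the unfolded protein and amino acid stress response, interferon-stimulated genes, class I antigen presentation, inflammatory cytokines, ABC transporters, NRF2 targets, chemotherapy targets, p53 targets, the BCL2 family, matrix genes, integrins, metalloproteinases, immediate early genes, heat shock proteins, ribosomal proteins, histones, Notch genes, Wnt targets, YAP/TAZ targets, lysosome and autophagy, and fibroblast, endothelial and leukocyte markers. Where 5 or more members were tested, camera (with a preset and with an estimated correlation between genes) and fry were run.

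Genes are named by a rule fixed beforehand. Per comparison it takes, among called protein-coding genes with mean CPM of at least 5 and no overlap between the libraries of the 2 groups, the 5 highest and 5 lowest log2 fold changes. It adds a panel of 22 stem cell, proliferation, hypoxia and receptor genes, and per called list up to 3 called members in its direction and 2 against. Genes at 0 counts in a group are given as a fold of at least the ratio to 3 counts, and genes at 1 to 3 counts as a ratio with an exact 95% interval.

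Alternatives were another scaling, no or a stricter count filter, all 16 libraries, the lines alone, a replicate block, leaving out each library, DESeq2, limma on log2 FPKM, and, chosen after the data were seen, a 10-library fit without the HCC1806 monolayers, voom quality weights, halved counts and list tests in reduced fits. The rule for named genes was also applied to the 10-library and BT474 fits after the data were seen.

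The test was tried on data simulated with equal spread in all groups, with 100 genes changed by 2-fold and 100 by 4-fold. At 2-fold and 4-fold edgeR recovered 1% and 28% in HCC1806 day 10 against monolayer (20389 genes run), 1% and 47% at day 20 (20388), 0% and 31% in day 20 against day 10 (20339), 1% and 46% in BT474 day 10 (20390) and 0% and 0% for the day 10 line difference (20365). The 10-library fit recovered 77% and 98% for HCC1806 day 20 against day 10 (20066 genes), BT474 alone 87% and 98% at day 10 (17066) and 88% and 99% for day 20 against day 10 (17044), and the subtype test 0% and 1% (17926). Unchanged genes called numbered 0 to 30 per run. The wider HCC1806 monolayer spread was not tried. Camera called a 2-fold change of 1 list of independent genes in every fit, which leaves correlated lists untested. The spheroid fits left out CAL148 and ZR-75-30. Results for some genes are not reported here.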

Results

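The series holds 16 RNA-seq libraries from 4 established human breast cancer cell lines, 2 libraries in each of 8 groups. HCC1806 and BT474 were each sampled as a monolayer and as spheroids 10 and 20 days after seeding. CAL148 and ZR-75-30 were sampled as monolayers alone. By general knowledge of these lines HCC1806 and CAL148 are triple-negative, lacking the oestrogen receptor, the progesterone receptor and ERBB2 amplification, and BT474 and ZR-75-30 are ERBB2-positive. Library totals ran from 29.7 M counts (CAL148 replicate 1) to 72.5 M (BT474 day 10 replicate 2). A floor of 3 counts therefore equals 0.0414 to 0.101 CPM (counts scaled to a common library total), depending on the library. Intervals and floors below cover counting error only. They take each count as independent, so the intervals are too narrow and the floors too low if both mates of a read pair were counted. Low counts are mostly even, as in that case. Expression is given as mean CPM on the normalised scale ± SD of n = 2 libraries, and changes as log2 fold change ± SE with the adjusted p of edgeR's quasi-likelihood test unless another tool is named. For gene lists p is that of camera with a preset correlation of 0.01 between genes, adjusted over the lists, and a second adjusted p is given with an estimated correlation. Member counts marked "over the list" are those with p adjusted over the list alone.

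The 2 HCC1806 monolayer libraries stood far apart. Mitochondrially encoded transcripts took 17.8% of the counts of replicate 1 and 0.768% of those of replicate 2, against 1.09% to 2.70% in the 4 HCC1806 spheroid libraries. The widest 95% Wilson interval of such a share spans 0.028 percentage points. Ribosomal protein genes took 13.5% and 4.20%. Interferon-stimulated genes were high in replicate 1: ISG15 stood at 2969 CPM in replicate 1 and 31.7 in replicate 2, between which lay the day 10 spheroids (176 and 159), and IFI6 stood at 1461 and 7.49. The cholesterol synthesis gene HMGCS1 (11 and 263 CPM) and the mitotic gene TOP2A (59.4 and 665 CPM) ran the other way, with the spheroids again in between. The SD of the log2 difference between replicates was 1.82 for this pair, 1.03 for ZR-75-30, 0.948 for CAL148 and 0.404 to 0.55 for the other 5 pairs. The second ZR-75-30 library also had a high mitochondrial share, 20.5% against 1.96%. For some lists and genes values without each monolayer library are given beside the HCC1806 comparisons. Such a fit holds 1 HCC1806 monolayer library, so its p includes no spread of that group.

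**Figure D1:**
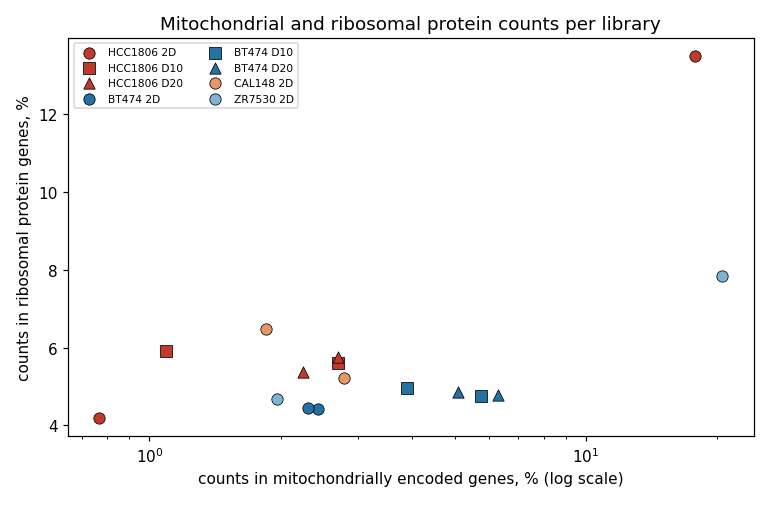
Percent of counts in mitochondrially encoded genes (horizontal, logarithmic) and in ribosomal protein genes (vertical), each point 1 of the 16 libraries, coloured by line and shaped by culture. HCC1806 monolayer replicate 1 (17.8%) and ZR-75-30 replicate 2 (20.5%) have the highest mitochondrial shares, and the BT474 spheroids (3.89% to 6.30%) lie above the BT474 monolayers (2.31% and 2.43%).

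The first comparison asks what 10 days of spheroid culture changed in HCC1806. DSG1 (ENSG00000134760, chromosome 18, 31318089 to 31357029 on GRCh38) had 265 counts over the 2 spheroid libraries and 0 over the monolayers, at least 67.4-fold higher against a floor of 3 counts over the group (adjusted p = 0.00388). The chloride channel regulator CLCA4 (ENSG00000016602, chromosome 1, 86547078 to 86580754) rose by 6.73 ± 0.47, from 0.688 ± 0.274 to 72.0 ± 6.49 CPM (adjusted p = 0.00174). CYP24A1 (ENSG00000019186, chromosome 20, 54153449 to 54173973), the vitamin D hydroxylase, rose by 7.18 ± 0.72, from 0.243 ± 0.110 to 34.2 ± 2.47 CPM (adjusted p = 0.0043). CD36 rose by 7.53 ± 1.10 (36.0 against 0.208 CPM, adjusted p = 0.00686) and CP by 7.04 ± 1.06 (22.5 against 0.175 CPM, adjusted p = 0.00766). RPTN had 1101 counts against 3, a ratio of 280 with a 95% counting interval of 95.5 to 1360, too narrow if both mates were counted (adjusted p = 0.0104). The collagenase MMP13 (ENSG00000137745, chromosome 11, 102942995 to 102955734) rose by 4.26 ± 0.25, from 2.26 ± 0.255 to 43.6 ± 2.99 CPM (adjusted p = 0.000216). Among the genes that fell, AREG (ENSG00000109321, chromosome 4, 74445134 to 74455009) changed by -3.23 ± 0.32 (3.87 ± 0.186 against 36.3 ± 14.2 CPM, adjusted p = 0.00206) and GAL by -3.26 ± 0.50 (8.56 against 82.2 CPM, adjusted p = 0.00775). PPP1R14A (-3.36, adjusted p = 0.0218), FST (-3.25, adjusted p = 0.0299) and KCNQ5 (-3.13, adjusted p = 0.0299) also fell. ERBB2 rose by 0.86 ± 0.20, to 216 ± 8.54 from 119 ± 4.09 CPM (adjusted p = 0.0309).

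Among 28 tested squamous differentiation genes 10 rose and 0 fell (11 and 0 over the list), including DSG1, SERPINB3 (10.6 against 0.137 CPM) and SERPINB4 (13.8 against 0.26 CPM), a near-identical pair whose reads may be shared (camera adjusted p = 2.72e-05, p = 0.372 with an estimated correlation). In the hypoxia response 6 of 26 genes rose and 1 fell (9 and 1 over the list): NDRG1 rose by 2.80 ± 0.26, to 1066 ± 23.5 from 153 ± 43.8 CPM, BHLHE40 by 1.99 and CA12 by 1.89, and BNIP3 changed by -0.76 (adjusted p = 0.0118, p = 0.372 with an estimated correlation). Of 24 DNA replication genes 9 fell and 0 rose (12 over the list), including GINS2 (-1.67 ± 0.20, 17.4 against 55.2 CPM), RRM2 (-1.54) and CDC45 (-1.49), with adjusted p = 7.94e-09, p = 0.372 with an estimated correlation. Only 2 of 27 mitosis genes passed, AURKB (-1.50) and UBE2C (-1.18), both lower (2 over the list, adjusted p = 0.0118, p = 0.751 with an estimated correlation). Of 30 nuclear genes of oxidative phosphorylation 3 fell and 0 rose (9 over the list), ATP5MC1 by -1.22, CYCS by -0.87 and CYC1 by -0.79, with a list median of -0.80 (adjusted p = 2.72e-05, p = 0.372 with an estimated correlation). Of 20 luminal markers 6 rose and 1 fell (7 and 1 over the list): FOXA1 by 2.15 (97.8 against 22.1 CPM) and CA12 were among those that rose, and KRT18 changed by -1.91 (adjusted p = 0.0277, p = 0.372 with an estimated correlation). Without monolayer replicate 2 the hypoxia (adjusted p = 0.137), replication (0.293), luminal (0.247) and squamous (0.365) lists did not pass, and the mitosis list reversed, with 20 genes higher and a median of 1.26.

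Of 18 ABC transporters 2 rose and 0 fell (4 over the list), ABCA12 by 1.90 and ABCC3 by 1.54 (adjusted p = 0.0183, p = 0.372 with an estimated correlation). ABCG2 (-3.79, adjusted p = 0.118) and ABCB1 (-0.28, adjusted p = 0.889) did not pass. Of 27 NRF2 targets 8 rose and 1 fell (8 and 2 over the list), CYP1B1 by 3.15, AKR1B10 by 2.43 and AKR1C2 by 2.08, with TXN at -0.97 (adjusted p = 0.0225, p = 0.372 with an estimated correlation). Without monolayer replicate 1 the adjusted p of CYP1B1 was 0.0523. Of 26 chemotherapy targets 5 fell and 0 rose (6 and 1 over the list), including UPP1 (-2.31, 7.59 against 37.6 CPM), TUBB6 (-1.24) and TUBB2A (-0.99), with adjusted p = 0.00676, p = 0.407 with an estimated correlation. The unfolded protein and amino acid stress response had 4 of 26 members falling and 0 rising (4 over the list), SLC7A5 by -1.44, SLC3A2 by -1.37 and SDF2L1 by -1.22 (adjusted p = 0.00676, p = 0.373 with an estimated correlation). Among 23 YAP/TAZ targets 4 fell and 0 rose (5 over the list), CYR61 (CCN1) by -2.39 ± 0.21 (7.80 ± 0.026 against 40.8 ± 5.04 CPM), FJX1 by -1.38 and GADD45B by -1.14 (adjusted p = 0.00676, p = 0.4 with an estimated correlation). Heat shock proteins had 4 of 19 falling and 0 rising (6 and 1 over the list), HSPE1 by -1.47, AHSA1 by -1.07 and STIP1 by -1.03 (adjusted p = 0.00324, p = 0.372 with an estimated correlation). Of 24 immediate early genes 2 fell, DUSP2 (-2.56) and FOSL1 (-2.41), and NR4A2 rose by 1.14 (3 and 1 over the list, adjusted p = 0.0225, p = 0.471 with an estimated correlation). Without monolayer replicate 1 the ABC transporter (adjusted p = 0.151), NRF2 (0.328), stress response (0.781) and immediate early lists (0.813) did not pass, and without replicate 2 the chemotherapy (0.935), YAP/TAZ (0.889) and heat shock lists (0.934). NRF2 targets also did not pass without day 10 replicate 1 (0.0519).

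Of 24 matrix genes 4 rose and 0 fell (4 over the list), including COL16A1 (1.49), LAMB2 (1.01) and COL6A1 (0.92), with adjusted p = 0.0029, p = 0.372 with an estimated correlation. Of 19 metalloproteinase and plasminogen genes 5 rose and 0 fell (5 over the list), MMP13, MMP7 by 3.27 and MMP28 by 2.48 among them (adjusted p = 0.00578, p = 0.372 with an estimated correlation). Of 25 lysosome and autophagy genes 6 rose and 0 fell (7 over the list), SQSTM1 by 1.54 ± 0.18 (650 against 224 CPM), LAMP2 by 1.30 and PSAP by 1.13 (adjusted p = 0.000946, p = 0.372 with an estimated correlation). No integrin of 17 passed (list median 0.68, adjusted p = 0.0464, p = 0.67 with an estimated correlation). The 13 mitochondrially encoded genes (median -3.02, 0 passed, adjusted p = 0.00578, p = 0.67 with an estimated correlation) and the 30 ribosomal protein genes (median -0.91, RPS2 alone passing at -1.18, 0 over the list, adjusted p = 0.000722, p = 0.68 with an estimated correlation) moved with the monolayer pair. Without replicate 1 their medians were 1.10 and 0.36, and without replicate 2 they were -3.96 and -1.51. The matrix (adjusted p = 0.494), metalloproteinase (0.186) and integrin lists (0.98, and 0.0538 without day 10 replicate 1) did not pass without monolayer replicate 1, nor the lysosome list (0.142) without replicate 2.

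Stem cell markers, the subject named in the series title, did not pass as a list: of 23 members 1 rose and 0 fell, with a median of 0.55, or 0.51 with a gene at 0 counts set to its bound (adjusted p = 0.117). CD44 stood at 1334 ± 56.8 CPM in spheroids against 793 ± 575 in monolayers (0.75, adjusted p = 0.301). Its change was 0.07 without monolayer replicate 1 and 1.81 without replicate 2. ALDH1A1 (1.59, adjusted p = 0.127), ALDH1A3 (0.73, adjusted p = 0.38) and SOX2 (1.74, adjusted p = 0.258) did not pass. Nor did SOX9 (0.67, adjusted p = 0.573), ITGA6 (0.68, adjusted p = 0.505), CD24 (0.48, adjusted p = 0.241) or PROM1 (0.241 against 0.12 CPM, adjusted p = 0.569). MKI67 (-1.23, adjusted p = 0.315), TOP2A (-0.27, adjusted p = 0.88), VEGFA (0.66, adjusted p = 0.48), EGFR (0.22, adjusted p = 0.686) and CTGF (-1.71, adjusted p = 0.19) did not pass either. Without replicate 1 and without replicate 2 MKI67 changed by -2.12 and 0.85, VEGFA by 2.05 and -0.03, TOP2A by -1.22 and 2.37 and EGFR by -0.28 and 0.82. In the same order SOX2 changed by 0.76 and 4.91, SOX9 by -0.215 and 2.83, ITGA6 by -0.16 and 2.40, ALDH1A3 by -0.01 and 1.99 and ALDH1A1 by 2.82 and 0.94. CA9 stood at 0.589 against 0.406 CPM, and VIM had 1 count against 7.

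The other lists did not pass in this comparison. The medians and adjusted p were -0.18 and 0.39 for glycolysis (0 rose, 1 fell), 0.54 and 0.39 for cell cycle arrest (2 rose, 3 fell), 0.19 and 0.39 for epithelial junctions (2 rose), 0.16 and 0.795 for mesenchymal genes (0 passed) and 0.16 and 0.424 for the ERBB2 amplicon (1 rose). They were -0.19 and 0.712 for cholesterol synthesis (1 fell), -0.08 and 0.655 for fatty acid synthesis (0 passed), 0.42 and 0.117 for inflammatory cytokines (2 rose), 0.03 and 0.77 for p53 targets (2 rose, 1 fell), 0.47 and 0.0699 for the BCL2 family (8 rose, 1 fell) and 0.04 and 0.76 for Wnt targets (1 rose). They were -0.13 and 0.655 for replication-dependent histones (1 rose, 2 fell), 1.02 and 0.0878 for fibroblast markers (0 passed), 0.36 and 0.262 for endothelial markers (0 passed) and -0.58 and 0.865 for leukocyte markers (0 passed, -0.34 with genes at their bound). Signs differed between measures for basal markers (median -0.03, mean 0.002, tested upward, adjusted p = 0.655), interferon-stimulated genes (0.03, mean -0.11, upward, adjusted p = 0.117), class I antigen presentation (-0.41, mean -0.37, upward, adjusted p = 0.795) and Notch genes (0.13, mean -0.02, upward, adjusted p = 0.265). Interferon-stimulated genes were 34 of 34 higher without monolayer replicate 1 (median 2.71) and 20 lower and 5 higher without replicate 2 (median -0.79).

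**Figure D2:**
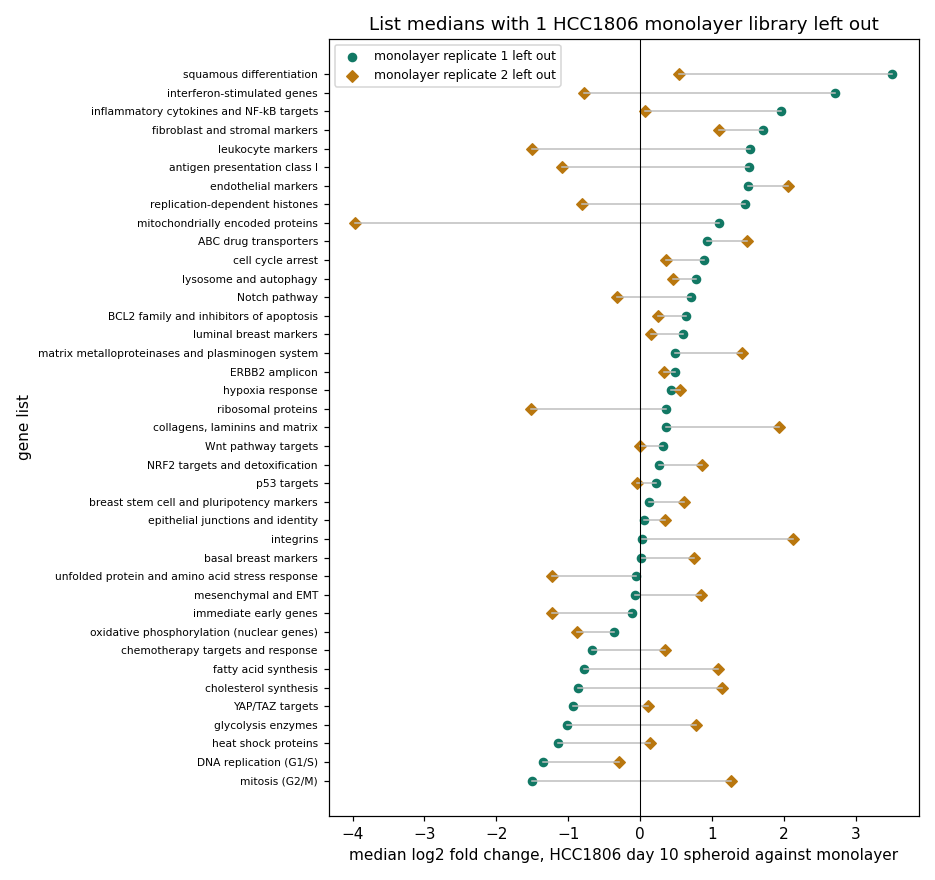
Median log2 fold change (horizontal) of each of the 39 gene lists (vertical) in HCC1806 day 10 spheroids against the monolayer, circles with monolayer replicate 1 left out and diamonds with replicate 2 left out. The mitosis list sits at -1.50 and 1.26, the mitochondrially encoded list at 1.10 and -3.96, and oxidative phosphorylation at -0.36 and -0.88.

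In all, 1076 genes were higher and 750 lower of 20929 tested, and 5461 had an unadjusted p under 0.05. A fit of the 6 HCC1806 libraries alone called 0 genes of 18869, with 2915 at an unadjusted p under 0.05. Over both days it kept 2 of 138 named calls. The 12-library fit shares its spread over all groups. The replicate SD was 1.82 for the HCC1806 monolayer pair and 0.404 to 0.55 for the other pairs of that fit. The adjusted p of that fit may therefore be too small for HCC1806 against monolayer, named genes included. Of the higher and lower genes 1055 and 741 were also called the same way without each monolayer library. Of the genes called in both fits with 1 monolayer library, 3438 had the same direction and 2632 opposite directions. The calls numbered 8617 without HCC1806 monolayer replicate 1, 11877 without replicate 2, 177 and 152 without day 10 replicate 1 or 2, and 884 and 882 without day 20 replicate 1 or 2. They numbered 1217 and 1249 without BT474 monolayer replicate 1 or 2, 853 and 848 without BT474 day 10 replicate 1 or 2, and 901 and 908 without BT474 day 20 replicate 1 or 2. Of 72 named called genes 9 passed in all 12 of these fits, among them DSG1, CLCA4, CYP24A1, MMP13, NDRG1, SQSTM1, AREG and CYR61. Across the 72 the adjusted p reached 0.31 in 1 of the fits while no sign changed. Of the 19 lists called, the oxidative phosphorylation list passed in all 12 fits (median -0.36 without monolayer replicate 1 and -0.88 without replicate 2). Mitosis genes reversed: 27 of 27 were lower without monolayer replicate 1 (median -1.50) and 20 were higher without replicate 2 (median 1.26). No list call of any comparison in the 12-library fit held with an estimated correlation.

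**Figure D3:**
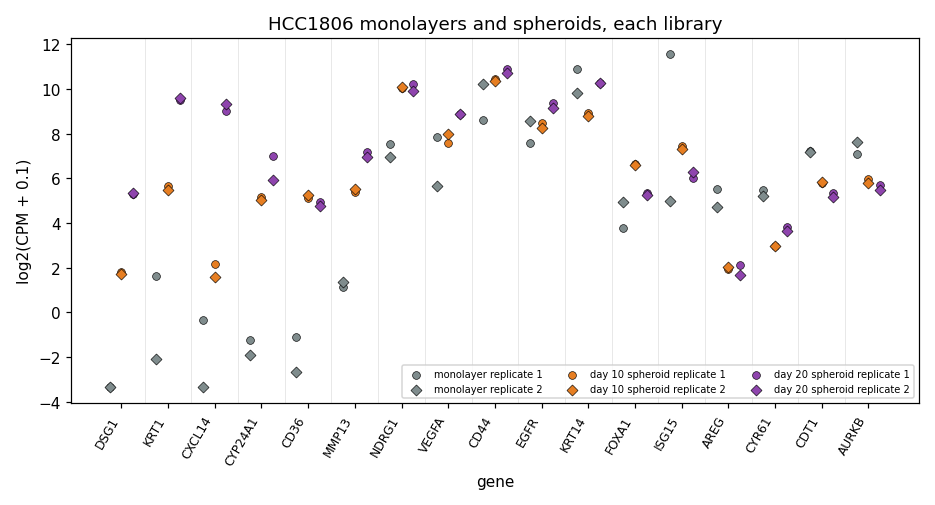
Expression per library, log2(CPM + 0.1), of 17 genes in the HCC1806 monolayers and the day 10 and day 20 spheroids, each point 1 library. DSG1 has 0 counts in both monolayers, and the monolayer points of ISG15 (2969 and 31.7 CPM) lie on either side of the spheroids.

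The second comparison sets 20 days of spheroid culture against the monolayer in HCC1806. DSG1 reached 39.8 ± 1.35 CPM on 3163 counts against 0, at least 815-fold higher (adjusted p = 0.00112). KRT1 (ENSG00000167768, chromosome 12, 52674736 to 52680407) rose by 8.96 ± 1.26, to 744 ± 29 from 1.55 ± 2.00 CPM (adjusted p = 0.00503). The chemokine CXCL14 (ENSG00000145824, chromosome 5, 135570679 to 135579279) rose by 10.89 ± 1.18, to 580 ± 83.5 from 0.34 ± 0.48 CPM (17 monolayer counts, adjusted p = 0.00207). DSG4 rose by 8.46 (24.2 against 0.0675 CPM, 4 monolayer counts) and CYP24A1 by 8.62 (93.1 against 0.243 CPM). AREG changed by -3.31 ± 0.32 (adjusted p = 0.00149), MT2A by -2.91 ± 0.50 (41.2 against 310 ± 171 CPM, adjusted p = 0.00989), PPP1R14A by -3.10 (adjusted p = 0.0224) and SPANXD by -2.85 (adjusted p = 0.0413). ATF5 changed by -2.81 (adjusted p = 0.0415), and by -0.79 without monolayer replicate 1. EGFR rose by 1.10 ± 0.29, to 614 ± 69.9 from 286 ± 134 CPM (adjusted p = 0.0467).

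Of the 28 squamous genes 10 rose and 0 fell (13 over the list, median 1.80, adjusted p = 4.76e-09, p = 0.318 with an estimated correlation). Stem cell and pluripotency markers passed as a list, with 3 of 23 members rising and 0 falling (5 over the list): NOTCH1 by 1.51 ± 0.22 (290 against 102 CPM), DLL1 by 1.14 and KLF4 by 0.84 (adjusted p = 0.0291, p = 0.515 with an estimated correlation). That call was lost without monolayer replicate 1 (adjusted p = 0.221). Of 21 Notch genes 4 rose and 0 fell (4 over the list), HES2 by 2.86 (211 against 29.2 CPM) and NOTCH3 by 1.51 among them (adjusted p = 0.046, p = 0.632 with an estimated correlation). It did not pass without monolayer replicate 2 (0.869) or day 20 replicate 2 (0.0574). Of 26 hypoxia genes 8 rose and 0 fell (12 over the list), EGLN3 by 3.38 (28.8 against 2.77 CPM), NDRG1 by 2.82 and CA12 by 2.33 (adjusted p = 0.000177, p = 0.318 with an estimated correlation). DNA replication genes had 13 of 24 falling and 0 rising (14 over the list), CDT1 by -1.93 ± 0.15 (37.9 against 145 CPM), GINS2 by -1.95 and CDC45 by -1.69 (adjusted p = 1.06e-10, p = 0.35 with an estimated correlation). Of 27 mitosis genes 5 fell and 0 rose (6 over the list), AURKB by -1.79, NDC80 by -1.53 and UBE2C by -1.49 (adjusted p = 0.000147, p = 0.685 with an estimated correlation). Oxidative phosphorylation genes had 5 of 30 falling and 0 rising (9 over the list), ATP5MC1 by -1.20, CYC1 by -0.78 and UQCRC1 by -0.70 (adjusted p = 7.21e-06, p = 0.318 with an estimated correlation).

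Of 18 ABC transporters 3 rose and 0 fell (5 over the list), ABCA12 by 2.19, ABCC5 by 1.43 and ABCC3 by 1.30 (adjusted p = 0.00966, p = 0.318 with an estimated correlation). Of 26 chemotherapy targets 5 fell and 0 rose (5 and 1 over the list), UPP1 by -2.23, STMN1 by -1.28 and TUBB4B by -1.14 (adjusted p = 0.0196, p = 0.632 with an estimated correlation). Of 26 stress response genes 4 fell and 0 rose (4 over the list), SLC7A5 by -1.52 and SDF2L1 by -1.33 among them (adjusted p = 0.0291, p = 0.632 with an estimated correlation). Of 19 heat shock genes 4 fell and 0 rose (6 over the list), HSPE1 by -1.39 (adjusted p = 0.0104, p = 0.614 with an estimated correlation). Of 24 matrix genes 5 rose and 0 fell (6 over the list), COL3A1 by 6.36 ± 0.97 (6.55 against 0.0686 CPM, 5 monolayer counts), COL5A2 by 2.44 and COL16A1 by 1.86 (adjusted p = 0.00384, p = 0.515 with an estimated correlation). COL3A1 and COL1A1 (1.34, 80.4 against 31.9 CPM) were the 2 of 11 fibroblast markers that rose, with 0 falling (2 over the list, adjusted p = 0.00929, p = 0.318 with an estimated correlation). Of 19 metalloproteinase genes 5 rose and 0 fell (5 over the list), MMP13 by 5.87 ± 0.26 (132 against 2.26 CPM), MMP7 by 4.50 and PLAT by 2.59 (adjusted p = 0.00765, p = 0.35 with an estimated correlation). One integrin of 17, ITGA1 (2.44, adjusted p = 0.0445), rose (0 over the list, adjusted p = 0.0291, p = 0.685 with an estimated correlation). Of 25 lysosome genes 6 rose and 0 fell (7 over the list), ATG9B by 2.65, SQSTM1 by 1.24 and CTSB by 1.22 (adjusted p = 0.0344, p = 0.685 with an estimated correlation). The mitochondrially encoded list (median -2.60, adjusted p = 0.03, p = 0.762 with an estimated correlation) and the ribosomal list (-1.05, RPS2 at -1.30, adjusted p = 0.000147, p = 0.685 with an estimated correlation) changed sign without monolayer replicate 1. The ABC (adjusted p = 0.0752), stress response (0.764), matrix (0.691), metalloproteinase (0.0957) and integrin lists (0.764) did not pass without monolayer replicate 1. The chemotherapy (0.909), heat shock (0.787), lysosome (0.862) and fibroblast lists (0.287) did not pass without replicate 2. Without day 20 replicate 1 the integrin (0.0737), lysosome (0.0532) and mitochondrially encoded lists (0.0572) did not pass.

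CD44 (1.17, adjusted p = 0.116), CD24 (0.84, adjusted p = 0.056), VEGFA (1.75, adjusted p = 0.0784), CDKN1A (1.04, adjusted p = 0.081), SOX9 (1.56, adjusted p = 0.178), SOX2 (1.58, adjusted p = 0.291) and ERBB2 (0.57, adjusted p = 0.101) did not pass. Without replicate 1 and without replicate 2 of the monolayer CD44 changed by 0.49 and 2.22, VEGFA by 3.15 and 1.06, SOX9 by 0.67 and 3.70, SOX2 by 0.59 and 4.74, CD24 by 1.10 and 0.58 and CDKN1A by 1.60 and 0.62. In total 1306 genes were higher and 1016 lower. As at day 10, the adjusted p may be too small, and calls that held without each monolayer library do not test the spread of that pair. The HCC1806 libraries alone gave 2 higher and 0 lower, with 3256 at an unadjusted p under 0.05. Between the fits with 1 monolayer library 3757 genes were called in the same direction and 2574 in opposite directions. The calls numbered 9034 and 11927 without HCC1806 monolayer replicate 1 or 2, 320 and 360 without day 20 replicate 1 or 2, and 1236 and 1232 without day 10 replicate 1 or 2. They numbered 1561 and 1578 without BT474 monolayer replicate 1 or 2, 1202 and 1196 without BT474 day 10 replicate 1 or 2, and 1254 and 1267 without BT474 day 20 replicate 1 or 2. Of 66 named called genes 17 passed in all 12 of these fits, among them DSG1, DSG4, KRT1, CXCL14, CYP24A1, MMP13, NDRG1, EGLN3, HES2, ABCA12, CDT1, GINS2, AURKB, UBE2C, UPP1 and AREG. Of 18 called lists squamous differentiation (median 1.32 to 4.72 over the fits), hypoxia (0.39 to 0.94), DNA replication (-1.59 to -0.50) and oxidative phosphorylation (-0.94 to -0.40) passed in all 12. Mitosis (0.93 without monolayer replicate 2), mitochondrially encoded (1.57 without replicate 1), ribosomal (0.32 without replicate 1), heat shock (0.08 without replicate 2), stress response (0.24 without replicate 1), chemotherapy (0.07 without replicate 2) and lysosome genes (-0.06 without replicate 2) changed sign.

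The direct test of day 20 against day 10 needs no monolayer. In the 12-library fit edgeR called 0 of 20929 genes, with 756 at an unadjusted p under 0.05, while DESeq2 called 89 higher and 41 lower. In a fit of the 10 libraries other than the HCC1806 monolayers, chosen after their spread was seen, 660 genes were higher and 742 lower of 20606, and the following values come from that fit. CXCL14 rose from 3.65 ± 1.03 to 580 ± 83.5 CPM (7.31 ± 0.22, adjusted p = 1.19e-07). PLA2G2A rose by 4.45 ± 0.21 (38.5 against 1.77 CPM, adjusted p = 1.19e-07), MMP10 by 4.55 ± 0.31 (22.7 against 0.971 CPM, adjusted p = 1.14e-05), CCDC3 by 4.46 ± 0.34 (adjusted p = 3.42e-05) and KRT1 by 3.98 ± 0.20 (744 against 47.4 CPM, adjusted p = 7.13e-06). MUC20 changed by -1.76 ± 0.11 (36.3 against 123 CPM, adjusted p = 7.52e-07), CEACAM6 by -1.80 (adjusted p = 0.00117), ADAMTS12 by -1.79 (adjusted p = 0.00036), TMEM71 by -1.79 (adjusted p = 0.00319) and STEAP1 by -1.74 (adjusted p = 0.00124). CD44 rose by 0.43 ± 0.09, to 1782 ± 146 from 1334 ± 56.8 CPM (adjusted p = 0.00805), with VEGFA at 1.10 ± 0.12 (467 against 219 CPM), EGFR at 0.89, SOX9 at 0.89 and CD24 at 0.37 also rising. TOP2A (-0.59), CDH1 (-0.41) and ERBB2 (-0.29) fell, and ALDH1A1 (-0.61, adjusted p = 0.365) did not pass. ITGA6 passed here (0.30, adjusted p = 0.0489) but not with monolayer replicate 2 alone added (0.0582) or replicate 1 alone added (0.0558), and ALDH1A3 did the opposite (-0.40, adjusted p = 0.0541 here, 0.0463 and 0.0451 there).

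Of 28 squamous genes 12 rose and 2 fell in the 10-library fit (19 and 3 over the list), DSG1 by 3.60 ± 0.21 and TGM3 by 2.48 against KRT13 (-0.51) and CSTA (-0.46), with adjusted p = 1.22e-13, p = 0.135 with an estimated correlation. Interferon-stimulated genes fell, 22 of 34 with 0 rising (27 over the list, median -0.76): IFI6 by -1.43 (122 against 330 CPM), ISG15 by -1.24 and OASL by -1.14 (adjusted p = 1.25e-23, p = 0.135 with an estimated correlation). Class I genes went the same way, 7 of 17 falling and 0 rising (12 over the list), PSMB10 by -0.91, B2M by -0.62 (1453 against 2243 CPM) and HLA-C by -0.53 (adjusted p = 6.84e-09, p = 0.0655 with an estimated correlation). Basal markers had 7 of 18 rising (8 over the list), CRYAB by 2.96, KRT6B by 2.02 and KRT14 by 1.41 (1215 against 460 CPM), and ITGB4 falling by 0.35 (adjusted p = 9.52e-08, p = 0.135 with an estimated correlation). Luminal markers had 6 of 20 falling and 3 rising (6 and 3 over the list), AGR2 by -1.50 (86.2 against 244 CPM), FOXA1 by -1.31 and MUC1 by -0.71 against TBX3 (0.56). The median was -0.17, the mean 0.11 and the test downward (adjusted p = 0.0021, p = 0.135 with an estimated correlation). NRF2 targets had 12 of 27 falling and 0 rising (14 over the list), ALDH3A1 by -0.99 and AKR1C2 by -0.87 (adjusted p = 9.52e-08, p = 0.135 with an estimated correlation). Of 27 mitosis genes 9 fell and 0 rose (24 over the list), CDC25C by -0.84 and TTK by -0.60 (adjusted p = 1.27e-13, p = 0.135 with an estimated correlation). Of 24 replication genes 4 fell and 0 rose (4 over the list), CDT1 by -0.56 (adjusted p = 0.000168, p = 0.503 with an estimated correlation).

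Of 26 hypoxia genes 5 rose and 0 fell (6 over the list), LOX by 1.71 and BNIP3 by 0.74 (adjusted p = 0.00011, p = 0.155 with an estimated correlation). Of 21 Notch genes 7 rose and 0 fell (8 over the list), HEYL by 1.41, HES2 by 1.23 and HEY2 by 1.08 (adjusted p = 0.00211, p = 0.141 with an estimated correlation). Of 19 Wnt targets 5 rose and 0 fell (6 over the list), APCDD1 by 3.34 and TNFRSF19 by 2.56 (adjusted p = 0.000578, p = 0.135 with an estimated correlation). Of 23 stem cell markers 6 rose and 1 fell (6 and 2 over the list), DCLK1 by 2.11 and DLL1 by 0.60 against ALCAM at -0.38 (adjusted p = 0.0209, p = 0.141 with an estimated correlation). Of 23 YAP/TAZ targets 6 rose and 0 fell (8 over the list), RBMS3 by 1.96 and CYR61 by 0.76 (adjusted p = 0.000379, p = 0.141 with an estimated correlation). Epithelial junction genes had 8 of 20 falling and 2 rising (8 and 2 over the list), TJP3 by -1.05 and CLDN7 by -0.54 against DSP (1.21) and CLDN1 (0.70), with adjusted p = 0.00285, p = 0.223 with an estimated correlation. Of 25 lysosome genes 10 fell and 0 rose (12 and 1 over the list), CTSS by -1.26 and CTSD by -0.89 (adjusted p = 6.64e-05, p = 0.141 with an estimated correlation). Fibroblast markers had 2 of 11 rising and 0 falling (4 over the list), COL3A1 by 3.42 and PDPN by 1.09 (adjusted p = 0.0021, p = 0.155 with an estimated correlation). Of 23 cholesterol synthesis genes 1 rose, IDI1 by 0.52 (10 over the list, adjusted p = 0.000127, p = 0.456 with an estimated correlation). Heat shock (2 rose, adjusted p = 0.0449, p = 0.485 with an estimated correlation), ribosomal (3 fell, adjusted p = 0.0167, p = 0.643 with an estimated correlation) and ERBB2 amplicon genes (2 fell, median -0.14, mean 0.14, adjusted p = 0.0439, p = 0.159 with an estimated correlation) passed in the 10-library fit but not in the 12-library fit, as did the stem cell list. The 12-library fit called 8 lists upward and 8 downward. Of these 16, squamous (median 0.51 to 1.25), interferon (-0.80 to -0.69), mitosis (-0.48 to -0.29) and NRF2 genes (-0.35 to -0.26) passed with any 1 of the 12 libraries left out. The call was lost by 9 lists without day 20 replicate 1, 7 without day 20 replicate 2, 2 and 5 without day 10 replicate 1 or 2 and 1, luminal markers (adjusted p = 0.0507 to 0.0571), without each BT474 library. The highest adjusted p were 0.252 for epithelial junctions (day 10 replicate 1 out), 0.195 for Notch (day 10 replicate 2 out) and, without day 20 replicate 1, 0.227 for cholesterol synthesis and 0.133 for luminal markers. Without an HCC1806 monolayer library edgeR called 1359 (replicate 1 out) or 1441 genes (replicate 2 out), and 0 with 1 of the other 10 left out.

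In BT474 the day 10 comparison asks the same question in an ERBB2-amplified luminal line. In the 12-library fit PIP (ENSG00000159763, chromosome 7, 143132077 to 143139746), the prolactin-induced protein, rose by 3.96 ± 0.23, to 140 ± 4.08 from 8.97 ± 1.67 CPM (adjusted p = 0.0186). LYZ (ENSG00000090382, chromosome 12, 69348341 to 69354234) rose by 5.73 ± 0.59 (17.2 against 0.322 CPM, adjusted p = 0.0261), KLK12 by 5.48 ± 0.54 (22.5 against 0.501 CPM, adjusted p = 0.0186) and LOXL4 by 3.47 ± 0.44 (225 against 20.3 CPM, adjusted p = 0.0366). APOD (chromosome 3, 195568702 to 195584205) had 1893 counts against 2, a ratio of 711 with a 95% counting interval of 196 to 5870, with the same limit (adjusted p = 0.0396). SMAD6 (chromosome 15, 66702228 to 66782848) changed by -3.08 ± 0.34 (3.58 against 30.3 CPM, adjusted p = 0.0228). ABCC3 changed by -2.17 ± 0.26 (58.4 against 262 ± 105 CPM, adjusted p = 0.031), STOM by -2.04 (adjusted p = 0.0333) and KIFC3 by -1.71 (adjusted p = 0.0228). The YAP/TAZ target AMOTL2 (chromosome 3, 134355874 to 134375479) changed by -1.59 ± 0.17 (23.3 against 70.1 CPM, adjusted p = 0.0228). The fit called 21 genes higher and 6 lower, with 1215 at an unadjusted p under 0.05. A fit of the 6 BT474 libraries alone called 1400 higher and 1147 lower.

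The following BT474 values come from the fit of its 6 libraries. CST1 rose by 4.33 (205 against 10.2 CPM, adjusted p = 0.0151) and SERPINA5 by 4.09 (adjusted p = 4.09e-06). ATOH8 (-3.73, adjusted p = 0.00537), CBLN2 (-3.48, adjusted p = 0.000459), FGD5 (-3.02) and PRRT1B (-2.92) fell. CD44 rose by 1.77 ± 0.11, to 47.0 ± 5.44 from 13.8 ± 0.158 CPM (adjusted p = 5.35e-06), SOX9 by 1.59 ± 0.14 (81.4 against 27.0 CPM), SOX2 by 1.64 ± 0.23 (6.42 against 2.06 CPM, adjusted p = 0.00101) and VEGFA by 0.96 (106 against 54.7 CPM). ALDH1A3 changed by -1.31 (1.29 against 3.20 CPM, adjusted p = 0.0106), CDKN1A by -0.88, and MKI67 by -0.77 ± 0.11 (77.2 against 131 CPM, adjusted p = 0.00104). With 11 libraries MKI67 did not pass (adjusted p = 0.207 without HCC1806 monolayer replicate 1, 0.193 without replicate 2). ERBB2 (-0.25, 5956 against 7066 CPM, adjusted p = 0.0492) did not pass without replicate 1 (0.0705) and passed without replicate 2 (0.0387). ALDH1A1 (-0.57, adjusted p = 0.331), PROM1 (-1.30, adjusted p = 0.0601), CD24 (0.24, adjusted p = 0.128) and ABCB1 (67 against 9 counts, adjusted p = 0.0503) did not pass. The stem cell list had a median of -0.01 and a mean of 0.07 but was called upward, with 5 of 18 members rising and 2 falling (5 and 3 over the list, adjusted p = 0.0276, p = 0.463 with an estimated correlation). With 12 libraries its median was -0.17 and it was tested downward (adjusted p = 0.659).

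Of 17 YAP/TAZ targets 10 fell and 1 rose (12 and 1 over the list, median -0.59): AMOTL2 by -1.59 ± 0.12, PTPN14 by -1.35 and AMOTL1 by -1.23 against GADD45B at 1.04 (adjusted p = 2.17e-09, p = 0.211 with an estimated correlation). Of 13 mitochondrially encoded genes 6 rose and 0 fell (13 over the list, median 1.14), MT-ND4L by 1.47 (924 against 333 CPM), MT-CYB by 1.24 and MT-ND4 by 1.19 (adjusted p = 5.33e-09, p = 0.463 with an estimated correlation). Of 27 mitosis genes 13 fell and 0 rose (15 over the list), MKI67, CENPF by -0.69 and PLK1 by -0.56 (adjusted p = 5.65e-08, p = 0.463 with an estimated correlation). Of 24 replication genes 4 fell and 0 rose (9 over the list), MCM5 by -0.40 (adjusted p = 0.00171, p = 0.683 with an estimated correlation). Of 32 interferon-stimulated genes 9 rose and 0 fell (12 over the list), OAS1 by 2.93 ± 0.32 (5.45 against 0.714 CPM), IFI6 by 1.95 (31.6 against 8.18 CPM) and IFI44 by 1.76 (adjusted p = 8.11e-06, p = 0.463 with an estimated correlation). Of 17 class I genes 6 rose and 0 fell (7 over the list), PSMB8 by 1.36 and PSMB9 by 1.34 (adjusted p = 0.00158, p = 0.463 with an estimated correlation). Of 23 hypoxia genes 11 rose and 1 fell (13 and 2 over the list), ADM by 1.09 and BHLHE40 by 1.08 against CA12 at -0.99 (adjusted p = 0.000245, p = 0.463 with an estimated correlation). Of 24 lysosome genes 10 rose and 1 fell (11 and 2 over the list), ATG9B by 2.46 and GRN by 0.82 against TFEB at -1.32 (adjusted p = 5.75e-05, p = 0.463 with an estimated correlation).

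Of 11 basal markers 5 rose and 1 fell (5 and 2 over the list), LAMA3 by 2.40, COL17A1 by 2.09 and KRT16 by 1.60 against CDH3 at -0.58 (adjusted p = 0.0162, p = 0.463 with an estimated correlation). Of 15 fatty acid synthesis genes 6 rose and 0 fell (6 and 2 over the list, median 0.09), THRSP by 2.96 and SCD by 1.05 (3475 against 1680 CPM, adjusted p = 0.0235, p = 0.463 with an estimated correlation). Cholesterol synthesis had 4 of 23 genes rising and 1 falling (6 and 1 over the list), INSIG1 by 0.72 among those that rose (adjusted p = 0.0481, p = 0.715 with an estimated correlation). Of 26 stress response genes 5 rose and 0 fell (10 over the list), DDIT4 by 1.18 (adjusted p = 0.00339, p = 0.463 with an estimated correlation). Of 30 ribosomal protein genes 10 rose and 0 fell (16 over the list), RPS23 by 0.55 (adjusted p = 0.000847, p = 0.498 with an estimated correlation). Of 22 immediate early genes 8 rose and 3 fell (9 and 3 over the list), PHLDA1 by 1.60 and DUSP6 by 1.03 against DUSP2 at -2.36 (adjusted p = 0.0213, p = 0.463 with an estimated correlation). With 12 libraries 5 lists were called upward and 3 downward. YAP/TAZ (median -0.56, adjusted p = 2.88e-09, p = 0.443 with an estimated correlation) and lysosome genes (0.24, adjusted p = 0.00515, p = 0.964 with an estimated correlation) passed in all 12 fits with 1 library left out. The other 6 each lost the call in 1 or more of them. Mitochondrially encoded (adjusted p = 0.145) and leukocyte genes (0.145) lost it without day 10 replicate 1, mitosis (0.181) and hypoxia genes (0.181) without day 10 replicate 2, interferon genes (0.356) without monolayer replicate 1 and replication genes (0.749) without monolayer replicate 2. Leukocyte markers were called through LYZ, the 1 of 6 that rose, with a median of 1.33, or 0.47 with genes at their bound. The gene calls numbered 0 without BT474 monolayer replicate 1, 3 without replicate 2, 0 without either BT474 day 10 library, 2 without either BT474 day 20 library, 1 without either HCC1806 day 10 library and 0 without either HCC1806 day 20 library. They numbered 2360 and 2443 without HCC1806 monolayer replicate 1 or 2.

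Day 20 spheroids of BT474 were set against the same monolayers. In the 12-library fit LYZ changed by 6.25 ± 0.60 (24.8 against 0.322 CPM, adjusted p = 0.0181), KLK12 by 5.98 ± 0.55 (31.7 CPM, adjusted p = 0.0179). SERPINA5 changed by 4.17 (10.1 against 0.561 CPM, adjusted p = 0.044), KLK11 by 3.90 (17.8 against 1.19 CPM, adjusted p = 0.02) and PIP by 3.88 (132 CPM, adjusted p = 0.0179). SMAD6 (-2.73, adjusted p = 0.0239), ABLIM1 (-2.29, adjusted p = 0.044), STOM (-2.11, adjusted p = 0.023), FSTL1 (-1.92, adjusted p = 0.044) fell, as did the tubulin TUBB6 (-1.92 ± 0.21, 7.35 against 27.8 CPM, adjusted p = 0.0179), PTPN14 (-1.55, adjusted p = 0.0436) and AMOTL2 (-1.43, adjusted p = 0.0229). The fit called 37 genes higher and 12 lower, with 1441 at an unadjusted p under 0.05, and the 6 BT474 libraries alone gave 1562 and 1509.

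In the fit of BT474 alone TFPI2 rose by 4.37 ± 0.20 (18.8 against 0.905 CPM, adjusted p = 5.47e-07) and CST1 by 4.37 (adjusted p = 0.013), and CBLN2 (-2.92), ATOH8 (-2.79), PRRT1B (-2.76) and FGD5 (-2.48) fell. CD44 stood at 50.9 CPM (1.89 ± 0.11, adjusted p = 3.37e-06), with SOX9 (1.33, adjusted p = 0.000121), SOX2 (1.02, adjusted p = 0.0133) and VEGFA (0.76, adjusted p = 0.000432) also higher. MKI67 (-0.94, 68.5 against 131 CPM), CDKN1A (-1.18), ALDH1A3 (-1.37) and CDH1 (-0.24) fell, and PROM1 (-1.55, 0.427 against 1.25 CPM, adjusted p = 0.0323) did not pass with 11 libraries (0.0789 without HCC1806 monolayer replicate 1, 0.0829 without replicate 2). Of 17 YAP/TAZ targets 11 fell and 1 rose (13 and 1 over the list, median -0.80), AMOTL1 by -1.83 and PTPN14 by -1.55 against GADD45B at 1.13 (adjusted p = 1.46e-09, p = 0.215 with an estimated correlation). Of 13 mitochondrially encoded genes 10 rose and 0 fell (12 over the list), MT-ND4L by 1.85 (1202 against 333 CPM) and MT-ND2 by 1.74 (adjusted p = 1.43e-12, p = 0.582 with an estimated correlation). Of 27 mitosis genes 11 fell and 0 rose (15 over the list), MKI67 and CENPF (-0.69) among them (adjusted p = 2.17e-05, p = 0.582 with an estimated correlation). Of 24 replication genes 2 fell (2 over the list, adjusted p = 0.0359, p = 0.797 with an estimated correlation). Basal markers had 5 of 11 rising and 3 falling (5 and 3 over the list), COL17A1 by 2.95 ± 0.22 (17.3 against 2.24 CPM) and LAMA3 by 2.31 against TRIM29 at -0.93 (adjusted p = 0.00753, p = 0.582 with an estimated correlation). Glycolysis genes had 6 of 17 falling and 1 rising (6 and 1 over the list), LDHA by -0.63, HK1 by -0.63 and HK2 by -0.40 against ENO2 at 0.77 (adjusted p = 0.0239, p = 0.693 with an estimated correlation). Of 26 stress response genes 7 rose and 0 fell (7 and 1 over the list), DDIT4 by 1.94 ± 0.12 (140 against 36.4 CPM, adjusted p = 0.00906, p = 0.582 with an estimated correlation).

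Of 30 ribosomal protein genes 12 rose and 1 fell (18 and 1 over the list), RPS23 by 0.65 against RPS2 at -0.24 (adjusted p = 0.00156, p = 0.693 with an estimated correlation). Of 19 histone genes 6 rose and 0 fell (7 over the list), HIST2H4A by 1.63 among them (adjusted p = 0.00753, p = 0.582 with an estimated correlation). Poly(A) selection captures few histone messages, and near-identical histone genes may share reads. Interferon-stimulated genes did not pass at day 20 (median 0.15, adjusted p = 0.211). In the 12-library fit YAP/TAZ (median -0.80, adjusted p = 5.99e-09, p = 0.4 with an estimated correlation) and mitochondrially encoded genes (1.35, adjusted p = 0.00407, p = 0.991 with an estimated correlation) were called, and both passed with any 1 of the 12 libraries left out. The gene calls numbered 0 and 1 without BT474 monolayer replicate 1 or 2, 2 and 0 without day 20 replicate 1 or 2, 2 without either BT474 day 10 library, 4 without either HCC1806 day 10 library and 6 without either HCC1806 day 20 library. They numbered 2892 and 2946 without HCC1806 monolayer replicate 1 or 2.

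**Figure D4:**
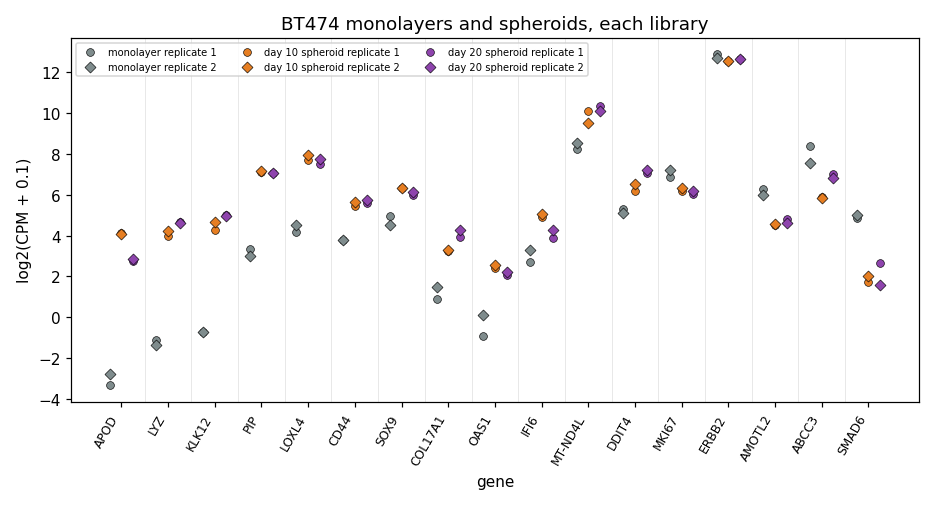
Expression per library, log2(CPM + 0.1), of 17 genes in the BT474 monolayers and the day 10 and day 20 spheroids, each point 1 library. PIP stands at 8.97 CPM in monolayers and at 140 and 132 CPM in day 10 and day 20 spheroids, and AMOTL2 falls by 1.59 and 1.43 on the log2 scale.

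Between day 10 and day 20 few BT474 genes were called. The edgeR test called 0 genes in 12 libraries, with 320 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 2 lower. The fit of BT474 alone called 6 higher and 21 lower. CERK (0.77 ± 0.10, adjusted p = 0.0192), DDIT4 (0.77, 140 against 82.5 CPM, adjusted p = 0.0306) and PKIG (0.75, adjusted p = 0.0353) rose in it. PLA2G2A (-1.61 ± 0.17, 18.3 against 55.7 CPM, adjusted p = 0.00583), KCNK3 (-1.73, adjusted p = 0.0166), MX1 (-1.23, adjusted p = 0.0353), NDRG1 (-1.03 ± 0.12, 81.3 against 166 CPM, adjusted p = 0.00842) and LDHA (-0.52, adjusted p = 0.0246) fell. APOD (-1.33, adjusted p = 0.023) passed without HCC1806 monolayer replicate 1 (0.0466) and not without replicate 2 (0.0619). EIF3C, which shares reads with its copy EIF3CL, fell by 1.33 (adjusted p = 0.00388) and did not pass with 11 libraries (0.529 and 0.563). The 12-library fit called 4 lists downward, each with 0 members passing there. They were hypoxia (median -0.22, adjusted p = 0.00102, p = 0.266 with an estimated correlation), cholesterol synthesis (-0.30, adjusted p = 0.0165, p = 0.963 with an estimated correlation), interferon (-0.38, adjusted p = 0.0165, p = 0.963 with an estimated correlation) and lysosome genes (-0.17, adjusted p = 0.0165, p = 0.963 with an estimated correlation). Of these, 3 lost the call without BT474 day 10 replicate 2, 3 without day 20 replicate 1, 3 without day 20 replicate 2 and 1 without day 10 replicate 1 (highest adjusted p = 0.344, lysosome genes without day 10 replicate 2). BT474 alone also called glycolysis (median -0.11, adjusted p = 9.86e-05, p = 0.563 with an estimated correlation), class I (-0.24, adjusted p = 0.000999, p = 0.548 with an estimated correlation) and fatty acid genes (-0.14, adjusted p = 0.000999, p = 0.548 with an estimated correlation) downward. It called mitochondrially encoded (0.32, adjusted p = 0.00305, p = 0.757 with an estimated correlation), NRF2 (0.10, adjusted p = 0.0113, p = 0.563 with an estimated correlation) and histone genes (0.20, adjusted p = 0.0107, p = 0.548 with an estimated correlation) upward. The edgeR test called 96 and 81 genes without HCC1806 monolayer replicate 1 or 2, and 0 with any other library left out.

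Whether the spheroid effect differed between the lines was tested directly, as the HCC1806 effect minus the BT474 effect. At day 10 SLC40A1 (ferroportin, chromosome 2, 189560579 to 189583758) differed by 3.71 ± 0.20 (adjusted p = 0.000457), moving up in HCC1806 to 102 from 15.3 CPM and down in BT474. TENM2 differed by 4.57 ± 0.38 (adjusted p = 0.00372), MMP13 by 6.20 ± 0.36 (adjusted p = 0.000457), BCAS1 by 6.47 (adjusted p = 0.0217), CEACAM5 by 5.92 (adjusted p = 0.0153) and IGFBP3 by 7.07 (adjusted p = 0.0452). PRSS23 differed by -4.47 ± 0.41 (adjusted p = 0.00503), moving down in HCC1806 to 25.0 from 86.8 CPM and up in BT474, and AREG by -3.61 ± 0.43 (adjusted p = 0.0112). FHL2 (-2.41), GADD45A (-2.37) and UPP1 (-2.22) also differed. NOTCH1 differed by 2.25 ± 0.31 (adjusted p = 0.0176), FOXA1 by 2.41 (adjusted p = 0.0454) and CA12 by 2.88. At day 20 PLA2G2A (8.46 ± 1.10, adjusted p = 0.0127), TENM2 (7.25 ± 0.39, adjusted p = 0.000342), BCAS1 (6.22), DNAJC6 (5.72, adjusted p = 0.00678) and CEACAM5 (5.63) differed upward, and PRSS23 (-3.62, adjusted p = 0.00885), KLK11 (-3.48), AREG (-2.89), SOX15 (-2.81) and TMSB10 (-2.62) downward. CDKN1A (2.22, adjusted p = 0.0483), EGLN3 (3.10) and LOX (3.07) differed upward, and CDT1 (-1.70), GINS2 (-1.57) and AURKB (-1.71) downward.

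At day 10, 200 genes differed upward and 82 downward, and at day 20 375 and 205. With 1 library left out the counts at day 10 were 39 and 48 without BT474 monolayer replicate 1 or 2, 8 and 10 without BT474 day 10, 56 and 58 without BT474 day 20, 11 and 18 without HCC1806 day 10 and 61 and 61 without HCC1806 day 20 replicates. At day 20 they were 86 and 59, 77 and 77, 20 and 11, 80 and 80, and 20 and 26 in the same order. Without HCC1806 monolayer replicate 1 or 2 the counts were 6279 and 10093 at day 10 and 6608 and 10213 at day 20. Of 23 named genes 4 were called in all 12 such fits at day 10, SLC40A1, TENM2 and MMP13 among them, and TENM2 was the 1 of 25 at day 20. Of 14 lists called at day 10 the oxidative phosphorylation list (median -0.68, adjusted p = 0.000166, p = 0.508 with an estimated correlation) passed in all 12 fits. At day 20, of 11 lists, oxidative phosphorylation (-0.73, adjusted p = 8.37e-05, p = 0.444 with an estimated correlation) and hypoxia (0.44, 6 of 26 members higher and 0 lower, 6, adjusted p = 0.000951, p = 0.401 with an estimated correlation) did.

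The log2 changes of the 2 lines were nearly unrelated across the 20929 genes, which are not independent replicates: Pearson r was 0.0212 at day 10 and -0.000718 at day 20, and Spearman rho 0.004 and -0.00879. The lines share no library. At day 10, 7 genes were called higher in both lines where 1.08 would be expected of independent lists (Fisher's exact test, p = 5.73e-05), 0 lower in both (0.215 expected) and 3 opposite (1.06 expected). At day 20, 10 were higher in both (2.31 expected, exact p = 6.38e-05), 1 lower in both (0.583) and 4 opposite (2.54). With the BT474 calls of the fit of that line alone, 154 genes at day 10 were higher in both (72 expected), 64 lower in both (41.1) and 126 opposite (109). At day 20 these were 204 (97.5 expected), 94 (73.3) and 204 (170). The BT474 fit tested 17447 genes, but these expected counts take 20929, so they are inexact and no p is given. With the same BT474 calls 104 and 136 of the genes with a mean of at least 5 CPM in each line were higher in both (59.9 and 73.9 expected). Of those genes 58 and 82 were lower in both (58.6 and 102 expected) and 98 and 155 opposite (119 and 174 expected). Without HCC1806 monolayer replicate 1 r was 0.0736 and 0.0494 with 661 and 610 genes higher in both (281 and 281 expected), 382 and 636 lower in both (176 and 304 expected) and 425 and 560 opposite (454 and 585 expected). Without replicate 2 r was -0.0307 and -0.0562, with 482 and 536 higher in both (406 and 451 expected), 181 and 243 lower in both (248 and 333 expected) and 1075 and 1322 opposite (635 and 778 expected).

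The monolayers of the 4 lines were compared by subtype, with the line as the replicate (2 against 2). The edgeR test called 0 of 18909 genes, with 1020 at an unadjusted p under 0.05. DESeq2 called 605 higher and 210 lower in the triple-negative lines and a fit of the 8 libraries with 1 coefficient per line called 1588 and 1455. The 8-library fit takes its error from replicate libraries within lines, so it tests these 4 lines and not subtype. ERBB2 (chromosome 17, 39687914 to 39730426) stood at 112 CPM in HCC1806, 320 in CAL148, 6850 in BT474 and 8736 in ZR-75-30, a difference of -5.20 ± 1.01 (adjusted p = 0.882). Its neighbours PGAP3 (-5.10), STARD3 (-4.63), GRB7 (-4.42) and MIEN1 (-4.38) had the same adjusted p of 0.882, and all 5 passed in the DESeq2 test and, as a difference between these lines, in the 8-library fit. The lines of a subtype differed among themselves. KRT5 stood at 2158 ± 1020 CPM in HCC1806 and 0 in CAL148, EGFR at 271 and 33.1, CD44 at 754 and 1.27, and SOX2 at 7.41 and 43.8. FOXA1 stood at 20.9 CPM in HCC1806 and 559 in CAL148, against 442 in BT474 and 501 in ZR-75-30. Between the ERBB2-positive lines PGR (504 and 0.17 CPM), CDH1 (812 and 8.69 CPM) and PROM1 (1.21 and 189 CPM) were far apart.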

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

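These results were singled out because the spheroid effect, HCC1806 minus BT474, passed a direct test of the line difference. Of the tests below, those of gene length and GC content for the monolayer pair and of the nuclear respiratory genes were chosen after the result was seen. At day 10 282 genes differed and at day 20 580.

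At day 10 the median log2 differences of the called lists were 0.59 for stem cell markers, -0.68 for oxidative phosphorylation, -4.05 for mitochondrially encoded genes, -0.70 for DNA replication, 0.54 for luminal markers, 1.85 for squamous genes, -1.14 for the stress response, -0.57 for chemotherapy targets, 0.66 for matrix, 0.85 for integrins, 0.73 for metalloproteinases, -1.004 for immediate early genes, -0.68 for heat shock and -1.08 for ribosomal proteins. At day 20 they were 0.78 for stem cell markers, 0.44 for hypoxia, -0.73 for oxidative phosphorylation, -3.95 for mitochondrially encoded genes, -0.74 for mitosis, -0.998 for replication, 2.43 for squamous genes, -1.05 for the stress response, 1.03 for integrins, -0.61 for heat shock and -1.14 for ribosomal proteins. None of these calls held with an estimated correlation (adjusted p = 0.401 to 0.85). With 1 of the 12 libraries left out in turn, 1 of the 14 lists kept its call throughout at day 10 and 2 of the 11 at day 20. The median changed sign in 1 or more of these fits for the mitochondrially encoded (up to 0.004), ribosomal (0.155), chemotherapy (0.263) and heat shock lists (0.012) at day 10. At day 20 it did so for the mitochondrially encoded (0.053), ribosomal (0.117) and mitosis lists (1.348). Gene differences at day 10 were IGFBP3 7.07, BCAS1 6.47, CEACAM5 5.92, TENM2 4.57, SLC40A1 3.71, PRSS23 -4.47, AREG -3.61, FHL2 -2.41, GADD45A -2.37 and UPP1 -2.22. At day 20 they were PLA2G2A 8.46, TENM2 7.25, BCAS1 6.22, DNAJC6 5.72, CEACAM5 5.63, PRSS23 -3.62, KLK11 -3.48, AREG -2.89, SOX15 -2.81, TMSB10 -2.62 and CDKN1A 2.22.

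The first pattern weighed is the difference between the 2 HCC1806 monolayer libraries. After removal of the trend with gene length and GC content the SD of their log2 difference was 1.69 (1.82 before), which argues against that trend as the whole cause. Genes exclusive to another line had, summed, at most 0.16% of that line's own level of them in either library, which argues against reads of another line. The design gives no group that separates the 2 libraries, so no biological explanation was tested.

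The second pattern is the fall of interferon genes and the rise of squamous genes between day 10 and day 20 in HCC1806, with the luminal list called downward. In the 10-library fit 6 of 20 luminal markers fell and 3 rose, with a mean of 0.11, and in 12 libraries their call was lost without any 1 BT474 library (adjusted p = 0.0507 to 0.0571). The trend with gene length and GC content was small: offsets for it moved log2 changes by an SD of 0.0369 over genes. The medians over all members were -0.755 for interferon, -0.166 for luminal and 0.979 for squamous genes before and -0.75, -0.162 and 1.012 after, and 100% of the called members were still called the same way. A trend of that size argues against length and GC bias as the whole cause. Genes exclusive to another line had, summed, at most 0.122% of that line's own level of them in a day 10 library, where the luminal and interferon genes called lower at day 20 than at day 10 would need a median of 393% to 1740%, which argues against reads of another line of the series. The remaining explanation the design offers is time in culture, which no test here separates from a difference between the libraries.

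The third pattern is the rise of mitochondrially encoded genes in BT474 spheroids. With offsets for gene length and GC content the smaller median was 86.2% of that before, and the called members went from 6 to 2 at day 10 and from 10 to 5 at day 20 as the median SE rose from 0.26 to 0.284 and from 0.263 to 0.287. Both medians met the written bound of 80%, but fewer than 80% of the called members stayed called. The test therefore cannot tell, and length and GC bias stays open. The change correlated with that of the ZR-75-30 library of high mitochondrial share at r = 0.104 at most across nuclear genes, which leaves a shared RNA state open. The nuclear respiratory genes had a median change of 0.025 at most, which argues against more respiratory chain components of both genomes.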

How the results depend on the processing

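The alternatives in which a count of calls moved by more than 1.5 times are given per setting, and the cause of a move was not tested unless stated. Without a count filter edgeR called 3406 genes in HCC1806 day 10, 3930 at day 20, 163 in HCC1806 day 20 against day 10, 423 in BT474 day 10, 424 at day 20, 16 in BT474 day 20 against day 10, 1390 and 1766 for the line difference at day 10 and day 20, and 1169 for subtype. The share of calls that were higher went from 58.9% to 48.4% in HCC1806 day 10, from 70.9% to 44.1% for the day 10 line difference and from 64.7% to 50% for that at day 20. A stricter filter gave 461 for the day 10 line difference. With all 16 libraries the counts in the same order were 834, 1076, 1, 9 and 11, and 36 and 85 for the line differences. With DESeq2 they were 3990, 4351, 130, 403, 457, 3, 1793 and 2122, and 815 for subtype. A fit of 8 libraries with a coefficient per line, which tests these lines and not subtype, gave 3043.

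HCC1806 alone gave 0 at day 10 and 2 at day 20. BT474 alone gave 2547, 3071 and 27. The residual spread of the 12-library fit includes that of the HCC1806 monolayer pair, and leaving that pair out, chosen after it was seen, gave 1402 for HCC1806 day 20 against day 10 and 2524, 3017 and 58 for BT474. Shared over all groups, that spread may be too large for comparisons without the pair and too small for those with it. Also chosen after the data were seen, voom with quality weights gave 59, 74, 1828, 1812, 2053, 496, 5 and 11 in the order above, and halved counts gave 3 for HCC1806 day 20 against day 10. Limma on log2(FPKM + 1) gave 105 for that comparison, 191 and 222 for BT474 against monolayer and 954 and 1382 for the line differences, and with 0.1 added 12, 71, 107, 663 and 1053. With a log2 scale of FPKM + 1 the KLK7 difference at day 20 reversed to 0.14.

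Replicate numbers did not pair the samples (correlation of deviations -0.124 to 0.0584 within lines). A replicate block gave 793 for HCC1806 day 10, 1133 for day 20, 0 and 0 for BT474 against monolayer and 14 and 16 for the line differences.

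With 1 library left out, which assumes that the lone library varies like the other groups, the counts ran from 152 to 11877 in HCC1806 day 10, 320 to 11927 at day 20, 0 to 1441 in day 20 against day 10, 0 to 2443 and 0 to 2946 in BT474 day 10 and day 20, 0 to 96 in BT474 day 20 against day 10, and 8 to 10093 and 11 to 10213 for the line differences. The lowest of those that moved were 1359 and 81 for the day 20 against day 10 tests. Lowest and highest medians are given for called lists whose median changed sign, and for others whose test reversed. Mitosis ran from -1.50 to 1.26 in HCC1806 day 10, -1.92 to 0.93 at day 20 and -1.56 to 1.35 for the day 20 line difference, and mitochondrially encoded genes from -3.99 to 1.10, -3.54 to 1.57 and -4.89 to 0.053 in the same order, with -5.08 to 0.004 for the day 10 line difference. Ribosomal proteins ran from -1.51 to 0.36, -1.65 to 0.32, and -1.62 to 0.16 and -1.80 to 0.12 for the line differences at day 10 and day 20. Heat shock proteins ran from -1.15 to 0.14 in HCC1806 day 10, -0.67 to 0.077 at day 20 and -1.09 to 0.012 for the day 10 line difference. Chemotherapy targets ran from -0.67 to 0.35, -0.75 to 0.072 and -0.96 to 0.26 in the same order. YAP/TAZ targets ran from -0.93 to 0.11 in HCC1806 day 10, lysosome genes from -0.059 to 0.73 at day 20, the stress response from -1.003 to 0.24 at day 20 and integrins from 0.029 to 2.13 at day 10. For the day 10 line difference squamous genes ran from 1.22 to 4.01, with 1.68 in the fit whose test reversed. The stem cell list at BT474 day 10 reversed in the test's direction in BT474 alone (median -0.006, adjusted p = 0.0276).

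In the gene list tests 0 of 92 calls held with camera and an estimated correlation, fry called 38, and 79 to 125 were called with 1 library left out. Over all alternatives 7445 gene results were unchanged, 1022 passed where they had not, 1715 no longer passed and 1 reversed, and for lists the numbers were 1744, 80, 294 and 17. The 10-library fit and that of BT474 alone were not rerun with a library left out. Depth limits genes under 0.0414 to 0.101 CPM.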

Other observations

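Gene families were tallied by symbol and tested after their values were seen. In HCC1806 the cornified envelope genes of chromosome 1 rose: 9 of 13 LCE genes at day 10 and 11 at day 20 (camera adjusted p = 3.36e-09 and 6.82e-12, and adjusted p = 0.464 and 0.417 with an estimated correlation), and 4 and 6 of 10 SPRR genes. LCE1A was at least 46.8-fold and 139-fold higher, and SPRR1A rose from 1.65 to 37.7 CPM at day 10. Of 49 MRPL genes 15 fell at day 10 and 21 at day 20 (camera adjusted p = 3.44e-13 and 3.13e-14, and adjusted p = 0.383 and 0.323 with an estimated correlation). In the fit of BT474 alone 6 and 7 of 9 KLK genes, a cluster on chromosome 19, rose (camera adjusted p = 3.76e-16 and 4.97e-18, and adjusted p = 0.962 and 0.889 with an estimated correlation), and KLK7 was at least 17.8-fold and 40.6-fold higher.

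Markers of other cell types varied by gene. Over the 16 libraries PTPRC reached 0.111 CPM, CD3E 0.0902 and PECAM1 0.541. COL1A1 stood at 61.3 to 111 CPM in the spheroids and 1.76 to 76.8 in the monolayers, and LYZ at 15.7 to 25.2 CPM in the BT474 spheroids. VWF reached 8.37 and ESAM 8.95 CPM in BT474. HCC1806 monolayer replicate 1 had CD14 at 6.70 and PDPN at 29.5 CPM (0.501 in replicate 2). Replicate 1 minus 2 of the HCC1806 and ZR-75-30 monolayers correlated at r = -0.446 across genes, which are not independent. The libraries of high mitochondrial share, replicates 1 and 2, tended to deviate alike.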
